A study of Mus musculus with 12 samples.

How the data were processed

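The samples were 12 Smart-seq2 libraries of poly(A) RNA from mouse embryos in 4 groups of 3, WT and maternal Pan2-deletion (KO) embryos at PN3 and L2C, grouped by the titles in the labels. The series design names zygotes and 2-cell embryos, while the labels' extraction protocol speaks of oocytes and 2-cell embryos. Per the labels' protocols, RNA at 0.2 ng per microlitre was used in volumes of 2.5 microlitres, primed with oligo(dT), pre-amplified for about 12 cycles, and 0.5 ng of cDNA was made into libraries sequenced as paired reads of 151 bases. Oligo(dT) priming needs a poly(A) tail, so a level here is that of RNA with a tail long enough to be primed, and total RNA was not measured. The sources used here name no spike-in, so levels are relative to the other genes of a library.

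The deposited values are raw counts per gene that the authors did not normalize, per the file headers and the values. Per the submitters' processing notes, Trim Galore 0.6.7, STAR 2.7.10a, featureCounts 2.0.2 and DESeq2 were used with the mm10 build. Strand and multi-mapping settings of the counting are not given in the sources used here, so levels of overlapping, antisense and closely similar genes are uncertain. The table held 55291 genes, of which 96.38% had a symbol in GENCODE M21. Coordinates are those of the deposited table.

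Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr (21160, with 34131 left out), libraries were scaled by TMM, and a robust quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, which share 1 estimate of the spread. The 5 comparisons were KO against WT at each stage, L2C against PN3 in each genotype, and the interaction, the KO effect at L2C minus that at PN3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Lists were tested in both directions with camera at a preset correlation of 0.01, adjusted over the 20 lists. Alternatives were camera with a correlation estimated per list, the rotation test fry, DESeq2 1.42.0, other scalings and filters, trends on gene length, a replicate block and leaving out each library. The tests, the 20 lists, the rule for named genes and these alternatives were chosen before the data were examined.

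The lists covered deadenylation, decapping with uridylation and exosome, poly(A) binding and polyadenylation, maternal oocyte factors, genes of the minor wave and regulators linked to the major wave of zygotic genome activation, ribosome biogenesis, ribosomal proteins, nuclear oxidative phosphorylation, mitochondrial mRNAs, replication histones, proteasome, spliceosome, cell cycle, p53 with apoptosis and DNA damage, chromatin regulators, the Hippo pathway, and markers of granulosa or cumulus cells, of sperm and of oviduct, stroma or blood. Named genes were Pan2 and, for each KO comparison, the 10 highest and 10 lowest log2 fold changes (5 and 5 for the stage comparisons) among called genes with a mean of at least 10 CPM in the higher group, no overlap of the 3 against 3 libraries (chance gives 10%) and a named symbol. For the interaction they were the 5 positive and 5 negative genes of lowest adjusted p under the same level and symbol conditions, for the overlap the 5 per direction with the largest smaller change, and for each list up to 4 members of lowest adjusted p, or the whole list where it had 6 or fewer tested members. For the classes, genes were called decay or zygotic at a log2 fold of 2 in WT with 1 library held out, and log2 CPM used a prior count of 2. CPM stands for counts per 1e6 counts of a library after TMM scaling.

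Same-numbered libraries of a stage deviated together from their group means. The correlations across genes were 0.165, 0.455 and 0.274 at PN3 and 0.128, 0.15 and 0.221 at L2C, each above 0.1, so numbers were taken to pair libraries within a stage, from the data and not from the labels. Some libraries correlated as much across numbers, at L2C replicates 1 and 2 (0.132 and 0.14) and at PN3 replicates 1 and 3 (0.205 and 0.211), so the numbers 1 and 2 at L2C and 1 and 3 at PN3 are not told apart by these values. Deviations within a group cancel out, so 1 library per group that deviates strongly makes the other libraries correlate between groups too. Replicate 2 at PN3 and replicate 3 at L2C, described below as rRNA-rich, are such libraries. The values therefore show that these libraries deviate together, and no pairing of the other numbers. Across stages the correlations were 0.0747, -0.162 and -0.176 in WT and 0.174, -0.255 and -0.248 in KO, so numbers were not taken to pair libraries there. A replicate block nested in the stage, centred within each stage, was added as an alternative after the data were seen. It was chosen from these same counts, so results with it are no separate support.

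Total counts ranged from 14453592 to 28624766 per library. Floors of 3 counts and counting intervals cover counting error only, since reads amplified by PCR are not independent molecules. The procedure was tested on simulated counts with 200 genes changed, all drawn from genes of at least 5 CPM in WT at the stage. Counts were drawn independently, so libraries that deviate together over many genes were not simulated. For L2C 8% of genes changed 2-fold and 65% of those changed 4-fold were called, and for PN3 5% and 76%, with 8 and 4 unchanged genes called. With no change simulated 0 genes passed in edgeR at either stage.

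The gene CT010467.1, an rRNA gene in GENCODE M21, took 34.9% and 32.2% of the counts in replicate 2 of WT and KO PN3, 24.0% and 34.0% in replicate 3 of WT and KO L2C, and between 4.35% and 13.9% in the other libraries. These 4 libraries are called rRNA-rich. Fits without them, with them as a covariate, with the trend on GC content removed, and with CT010467.1 left out were added after the data were seen. For pairs of replicates the mean chi-square of counts over genes was 3.39 and 3.70 for replicates 1 and 2 of WT and KO L2C and between 17.8 and 718 for the other pairs. Those 2 pairs differed by more than sampling noise, as separately amplified libraries of 1 pool would too, and the labels do not state their pools. They were kept as separate libraries, so n = 3 at L2C counts libraries and not samples known to be separate, and an alternative chosen after the data were seen summed them. Results of some genes are not reported here.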

Results

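Poly(A) RNA was measured by Smart-seq2 in mouse embryos with a maternal Pan2 deletion, here called KO, and in wild-type embryos, here called WT. Pan2 encodes the catalytic subunit of the PAN2-PAN3 deadenylase, which shortens the poly(A) tails of mRNA. Zygotes (PN3 in the labels) and 2-cell embryos (L2C in the labels) were profiled, with 3 libraries in each of the 4 groups. Total counts per library ranged between 14453592 and 28624766, with the PN3 libraries the deeper ones. A count of 3 in a library equals between 0.109 and 0.171 CPM, the count scaled to library size as described under processing. The labels do not state separate pools or animals for the replicates, so p-values measure only the spread between these libraries, technical or biological.

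The targeted gene was examined first. Pan2 (chromosome 10, 128303335 to 128321358, mm10) stood at 174 ± 14.6 CPM in WT PN3 and 4.26 ± 2.56 CPM in KO PN3 (SD, n = 3 each), a log2 fold change of -5.36 (SE 0.49, edgeR adjusted p = 0.00128). At L2C it stood at 63.8 ± 4.72 CPM in WT and 22.5 ± 10.4 CPM in KO (SD, n = 3 each), a log2 fold change of -1.50 (SE 0.41, edgeR adjusted p = 0.0255). Pan2 counts in the KO libraries lay between 39 and 119 at PN3 and between 268 and 688 at L2C. Between the stages Pan2 fell by 1.44 on the log2 scale in WT (edgeR adjusted p = 0.00798) and rose by 2.41 in KO (edgeR adjusted p = 0.000476). The labels do not say which part of the gene was deleted, so reads outside that part are not separated from intact transcripts. Counts per gene also do not separate transcripts of the maternal copy from those of the paternal copy. The L2C call was lost without WT L2C replicate 1 (edgeR adjusted p = 0.0687), 2 (0.0659) or 3 (0.0625) and without KO L2C replicate 1 (0.101) or 2 (0.0988).

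**Figure D1:**
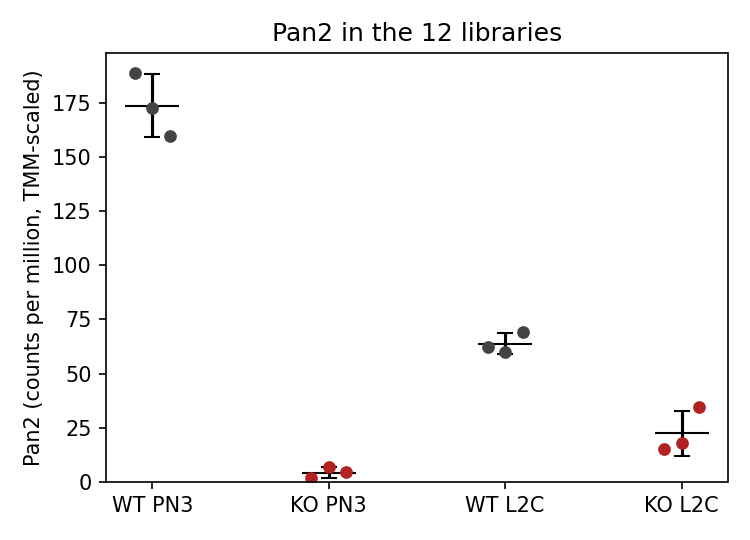
Pan2 level per library in CPM (linear axis from 0) for the 4 groups. Points are libraries, and the black bar and whiskers are the mean and SD of 3 libraries. The KO PN3 mean is 4.26 against 174 in WT PN3, and the KO L2C mean is 22.5 against 63.8 in WT L2C.

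The first comparison asked how zygotes differed with maternal Pan2 deletion. Besides Pan2, transcripts of Glb1, the lysosomal beta-galactosidase, and of Gipc2, a PDZ-domain protein, were lower in KO. Gipc2 stood at 151 ± 11.2 CPM in WT PN3 and 59.6 ± 3.64 CPM in KO PN3 (SD, n = 3 each). Bub1b, a spindle checkpoint kinase, was higher, at 223 ± 52.8 CPM in WT PN3 and 557 ± 53.2 CPM in KO PN3. Taldo1, an enzyme of the pentose phosphate pathway, was higher as well, at 19.25 ± 2.49 CPM and 62.2 ± 9.10 CPM.

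Of 21160 genes tested, 28 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 19 higher and 9 lower in KO, each of them by at least 2-fold, and 2144 had an unadjusted p under 0.05. Taldo1 (chromosome 7, 141392199 to 141402968) changed by a log2 fold change of 1.69 (SE 0.20, edgeR adjusted p = 0.0122), Bub1b (chromosome 2, 118598211 to 118641591) by 1.32 (SE 0.21, edgeR adjusted p = 0.0315) and Glb1 (chromosome 9, 114401076 to 114474898) by -1.98 (SE 0.28, edgeR adjusted p = 0.0154). Cdc5l, a splicing factor, stood at 0.62 ± 0.66 CPM in WT PN3 and 27.25 ± 18.3 CPM in KO PN3 (log2 fold change 5.38). The log2 fold changes of the other named genes were 2.53 for Mfhas1, 2.11 for Efna1, 1.86 for Tmem159, 1.51 for Klhl12, 1.39 for Dppa5a, 1.39 for Gli2, 1.34 for Marchf7 and -1.34 for Gipc2. The count was 566 (303 higher, 263 lower) with a replicate block within stages and 538 by DESeq2. It was 2, 5 and 16 without WT PN3 replicate 1, KO PN3 replicate 1 and KO PN3 replicate 3, 1 without WT PN3 replicate 3, and 2038 without the rRNA-rich libraries described under processing. All libraries share 1 estimate of the spread, and at L2C that last fit keeps only the close pairs of replicates described under processing. Their small differences therefore enter the PN3 test as well. With only the PN3 groups in the fit 2 genes passed, and with each close L2C pair summed 1 passed. Of the 13 named genes Pan2 alone kept its call in each of the 6 fits without 1 library. By edgeR adjusted p, Taldo1 lost its call without WT replicate 1 (0.054) or 3 (0.0807), Cdc5l without WT replicate 3 (0.0896) or KO replicate 1 (0.0541), Bub1b without WT replicate 1 (0.151) or 3 (0.146) or KO replicate 1 (0.141) or 3 (0.092), Glb1 without the same libraries (0.1, 0.0896, 0.0754 and 0.0586) and Gipc2 without the same libraries (0.0903, 0.103, 0.106 and 0.066). The other named genes lost theirs without WT replicates 1 and 3, with an adjusted p of up to 0.166, and Gli2, Tmem159 and Marchf7 also without WT replicate 2 (0.0784, 0.0784 and 0.0756). Without KO replicate 1 the adjusted p was 0.0584 for Mfhas1, 0.0699 for Efna1, 0.0787 for Klhl12, 0.157 for Gli2, 0.141 for Tmem159 and 0.163 for Marchf7, and without KO replicate 3 it was 0.0852, 0.071 and 0.125 for the last 3.

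Of the 20 gene lists, 0 passed the camera test at PN3, where the lowest unadjusted p was 0.0604, so that 0 lay under 0.05, and 0 passed with an estimated correlation or by fry. The list of chromatin regulators passed without WT PN3 replicate 2 (camera adjusted p = 0.012) and the list of maternal oocyte factors without KO PN3 replicate 2 (camera adjusted p = 0.00785). In the deadenylation list 0 of 25 members passed, over all genes and adjusted over the list alone, and the same numbers were 0 of 56 for maternal oocyte factors and 0 of 90 for ribosome biogenesis. Bub1b was the 1 call in the cell cycle list. Adjusted over the list alone, calls were also made for Dcp1a, a decapping cofactor (394.5 CPM in WT PN3 and 815 CPM in KO PN3), for Cpeb1, which regulates cytoplasmic polyadenylation (207 and 392 CPM), for Elf3 (16.3 and 39.3 CPM), Kdm5b (7.36 and 14.3 CPM), Usp17lc, Rpsa, Rps3, Bid and Pmaip1, all higher in KO, and for Ddit3 (28.2 and 12.8 CPM) and Gm4340, lower in KO. Over all genes these missed the threshold, with edgeR adjusted p of 0.0998 for Dcp1a, 0.119 for Cpeb1, 0.0548 for Elf3 and 0.0507 for Rpsa. With the replicate block the edgeR adjusted p was 0.0026 for Dcp1a, 0.00607 for Cpeb1, 0.012 for Elf3, 0.0183 for Kdm5b, 0.0103 for Usp17lc, 0.0033 for Rpsa, 0.00864 for Rps3, 0.0456 for Pmaip1 and 0.0252 for Ddit3. List medians and means differed in sign for ribosome biogenesis, ribosomal proteins, nuclear oxidative phosphorylation, granulosa or cumulus markers and sperm markers. In simulated libraries of this depth and spread, 5% of genes changed 2-fold and 76% of genes changed 4-fold were called without a block. Only genes of at least 5 CPM in WT PN3 were changed there.

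The second comparison asked how 2-cell embryos differed. Transcripts for ribosomal proteins were lower in KO: 67 of 88 were lower and 0 higher, with a median log2 fold change of -1.36. For this list camera with an estimated correlation gave an adjusted p = 0.0727. Of 90 ribosome biogenesis genes 59 were lower and 0 higher, with a median of -1.09. Of 56 maternal oocyte factors 17 were higher, 2 lower and 37 not called, with an adjusted p = 0.518 for the list with an estimated correlation. Fthl17e, a ferritin-like gene on the X chromosome, stood at 17.7 ± 3.33 CPM in WT L2C (SD, n = 3) and had 0 counts in KO L2C.

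Of 21160 genes tested, 3593 passed in edgeR, 1531 higher and 2062 lower in KO, of which 1232 and 1754 changed by at least 2-fold. With upper quartile scaling, which moved the median of all genes by 0.21 on the log2 scale, 2307 were higher and 1496 lower, so the balance between increases and decreases depended on the scaling. The directions of ribosomal proteins, ribosome biogenesis and maternal oocyte factors were the same under the 4 scalings, with 58 or more ribosomal protein genes lower and 12 or more maternal factors higher in each. With a replicate block within stages the count was 6815 (3152 higher, 3663 lower). By the chi-square of counts, replicates 1 and 2 of each L2C group were closer to each other than any other pair of replicates within a group. With both summed to 1 sample per group 379 genes passed. Named genes and lists were not examined in that fit. The count was 1620 and 1574 without WT L2C replicates 1 and 2, 1861 and 1841 without KO L2C replicates 1 and 2, and 9524 without the rRNA-rich libraries, which leaves those close pairs alone.

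Among named increases, Crmp1, a cytosolic phosphoprotein known from neurons, stood at 0.79 ± 0.52 CPM in WT L2C and 14.6 ± 6.75 CPM in KO L2C (SD, n = 3 each), a log2 fold change of 4.21 (SE 0.63, edgeR adjusted p = 0.00131). Tpp1, a lysosomal peptidase, stood at 2.7 ± 1.06 and 25.3 ± 11.4 CPM, a log2 fold change of 3.23 (SE 0.43, edgeR adjusted p = 0.000903), and Nadsyn1, an NAD synthetase, at 2.17 and 19.8 CPM (log2 fold change 3.18). The log2 fold changes of the other named increases were 3.73 for Trpm4, 3.72 for Smco4, 3.50 for Fxyd6, 3.43 for Ascl2, 3.41 for Dusp2, 3.26 for Bdnf and 3.25 for Foxl2. Fthl17e (chromosome X, 9033493 to 9034333) was at least 331-fold lower in KO against a floor of 3 counts over the group, and by the same measure the kinase gene Stk33 was at least 218-fold and Fthl17b at least 197-fold lower. Ube2dnl1 had 1 count in KO L2C, a ratio of 1095 with a 95% counting interval from 196.1 to 43280. Fthl17f stood at 133 ± 64.6 CPM in WT L2C and 7.62 ± 2.32 CPM in KO L2C, a log2 fold change of -4.12 (SE 0.54, edgeR adjusted p = 0.00122), Fthl17d at 20.8 and 0.11 CPM, Tsga8 at 56.7 and 1.46 CPM and Arrb1, a beta-arrestin, at 12.2 and 0.25 CPM. Spesp1 (log2 fold change -4.13) and Cpn1 (-3.998) completed the named decreases. The copies of Fthl17 are similar in sequence and the treatment of shared reads is not given in the sources used here, so the level of each single copy is uncertain. Smco4, Ascl2, Bdnf, Foxl2, Spesp1 and Cpn1 each lost their call without WT L2C replicate 1 (edgeR adjusted p = 0.0862, 0.111, 0.0583, 0.0885, 0.0719 and 0.0835), and the other 14 kept theirs in each of the 6 fits without 1 library. Smco4, Ascl2, Foxl2, Spesp1 and Cpn1 lost it without WT replicate 2 (0.0738, 0.0952, 0.11, 0.0693 and 0.0881) and Smco4, Ascl2, Foxl2 and Cpn1 without WT replicate 3 (0.079, 0.0597, 0.0797 and 0.0776). Calls were also lost without KO replicate 1 for Ascl2, Foxl2, Spesp1 and Cpn1 (0.091, 0.0529, 0.0721 and 0.0739), without KO replicate 2 for Ascl2, Bdnf, Foxl2 and Cpn1 (0.0944, 0.0546, 0.0639 and 0.103) and without KO replicate 3 for Smco4 and Foxl2 (0.0576 and 0.0777). Leaving out replicate 1 or 2 of a group keeps the other replicate of the close pair. These are not known to be separate samples, so a call kept in those fits may not hold over separate samples.

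Within the ribosomal protein list, Rpl10a stood at 323 ± 6.16 CPM in WT L2C and 66.8 ± 10.99 CPM in KO L2C (SD, n = 3 each) and Rps7 at 292 ± 9.58 and 97.9 ± 5.64 CPM. Within ribosome biogenesis, Imp3, a nucleolar protein of pre-rRNA processing, stood at 240.1 and 66.6 CPM, and Polr1e, a subunit of RNA polymerase I, at 135.4 and 24.95 CPM. Among regulators linked to the major wave of zygotic genome activation 11 of 37 were lower and 1 higher, including Nr5a2 (88.6 and 41.4 CPM) and Gabpa (213 and 64.8 CPM). Camera called 7 lists, and the calls that held with an estimated correlation were ribosome biogenesis (adjusted p = 0.00181) and the major activation regulators (adjusted p = 0.0435). Ribosomal proteins passed with the preset correlation (camera adjusted p = 1.76e-31) and had an adjusted p = 0.0727 with an estimated correlation, or 0.0458 when the replicate block was added. The proteasome (19 of 48 lower, 1 higher), the spliceosome (19 of 47 lower, 1 higher) and nuclear oxidative phosphorylation genes (25 of 88 lower, 1 higher) each had an adjusted p = 0.104 with an estimated correlation, and 0.0494, 0.0458 and 0.0458 when the block was added. Examples are the proteasome subunit Psma6 (178 and 37.1 CPM) and the spliceosome protein Snrpa (134 and 47.7 CPM). Maternal oocyte factors had a camera adjusted p = 0.000121 with the preset correlation, and lost that call with an estimated one (adjusted p = 0.518). Adjusted over the list alone, 77 ribosomal protein genes were lower and 1 higher, 77 ribosome biogenesis, 24 proteasome, 22 spliceosome and 35 oxidative phosphorylation genes were lower, 11 major activation regulators were lower, and 23 maternal oocyte factors were higher.

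**Figure D2:**
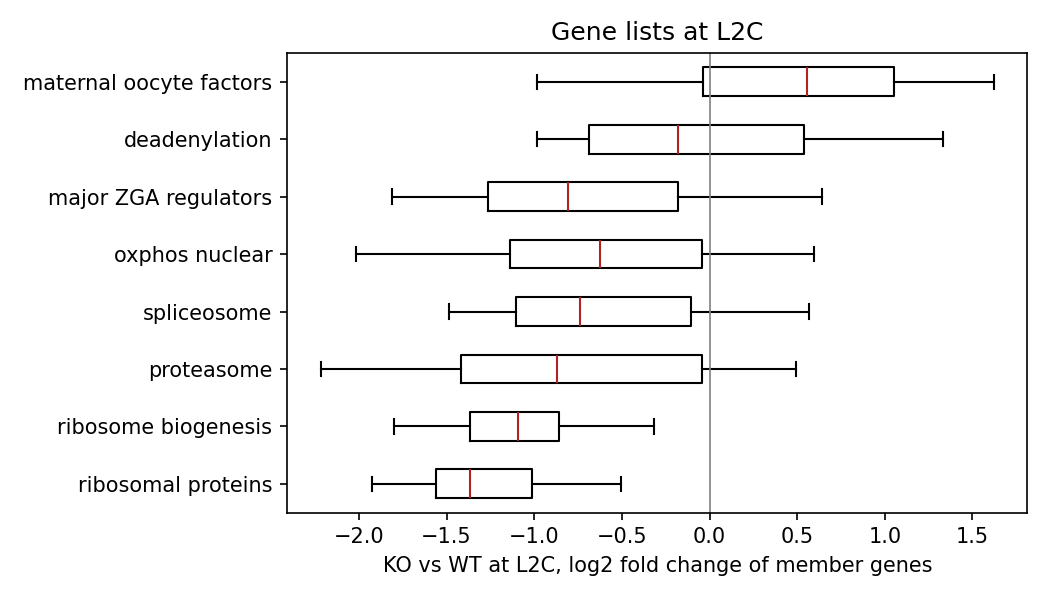
Log2 fold change of KO against WT at L2C for the member genes of 8 lists. Boxes span the quartiles, red lines are the medians, and whiskers leave out the lowest 5 and the highest 5 percent of members. The median is -1.36 for ribosomal proteins and 0.56 for maternal oocyte factors, and both keep their sign under the 4 scalings, while the deadenylation median turns positive with upper quartile scaling.

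Genes acting on poly(A) tails went both ways at L2C. In the deadenylation list 5 of 25 members were higher and 5 lower (6 and 5 adjusted over the list alone), and camera gave an adjusted p = 0.982. Cnot6l, a catalytic subunit of the CCR4-NOT deadenylase, stood at 89.3 ± 6.30 CPM in WT L2C and 225 ± 22.4 CPM in KO L2C (SD, n = 3 each), a log2 fold change of 1.33 (SE 0.19, edgeR adjusted p = 0.00105). Cnot4 was higher as well, while Zfp36, which recruits deadenylases to AU-rich mRNAs, fell from 41.02 to 14.2 CPM and Cnot9 from 51.4 to 26.3 CPM. Among decapping, uridylation and exosome genes 2 of 44 were higher and 10 lower (5 and 13 adjusted over the list alone, camera adjusted p = 0.526), including the exosome subunits Exosc5 (66.2 and 22.9 CPM) and Exosc1. Among poly(A) binding and polyadenylation genes 4 of 32 were higher and 8 lower (4 and 8 adjusted over the list alone, camera adjusted p = 0.7), including Pabpc1l (8.07 and 20.03 CPM) and the cleavage factor gene Cstf3 (45.8 and 10.7 CPM). The rotation test fry called the decapping and the poly(A) list lower in KO (fry adjusted p = 0.000447 and 0.0136). It did not call the deadenylation list (fry adjusted p = 0.592). The medians of the deadenylation and poly(A) lists turned from negative to positive with upper quartile scaling. Nobox, a transcription factor of oocytes, was higher in KO (12.7 and 45.2 CPM), as were Zar1 and Plat, while Zp3, a zona pellucida glycoprotein, fell from 85.0 to 33.9 CPM.

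Of the remaining lists none passed camera at L2C with TMM scaling. With DESeq2 size factors the minor wave of zygotic activation (camera adjusted p = 0.0431) and cell cycle genes (0.0317) passed, and with upper quartile scaling the minor wave (0.0435). Genes of the minor wave of zygotic activation gave 2 of 45 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.0546, and 0.000498 with the replicate block, or 0.517 with an estimated correlation added), among them Zfp750 (14.9 and 48.0 CPM) and Usp17lb (524 and 117 CPM). Cell cycle genes gave 5 of 54 higher and 12 lower, 6 and 14 adjusted over the list alone (camera adjusted p = 0.058, and 0.0189 with the block, or 0.0893 with an estimated correlation added), including Orc1, a subunit of the replication origin complex (55.3 and 15.2 CPM). The minor wave also passed without WT L2C replicate 3 (camera adjusted p = 0.00239), KO L2C replicate 1 (0.00533) or KO L2C replicate 2 (0.00267), and cell cycle genes without WT L2C replicate 3 (0.0386) or KO L2C replicate 1 (0.0468). Replication histones gave 4 of 38 higher and 0 lower (camera adjusted p = 0.239), mitochondrial mRNAs 0 of 13 (0.703), p53, apoptosis and DNA damage genes 2 of 36 lower and 0 higher (0.59), chromatin regulators 1 of 49 higher and 8 lower (0.982), and Hippo pathway genes 3 of 18 higher and 4 lower (0.751). Adjusted over the list alone these were 3 higher for histones, 0 for mitochondrial mRNAs, 2 lower for p53 genes, 2 higher and 8 lower for chromatin regulators and 3 higher and 5 lower for Hippo genes. Atf4, a stress-response transcription factor, fell from 213 to 102 CPM. Markers of granulosa or cumulus cells gave 1 of 14 higher (Foxl2) and 1 lower (Npr2), markers of sperm 1 of 9 higher (Odf2) and 2 lower (Oaz3 and Ldhc), and markers of oviduct, stroma or blood 2 of 14 higher (Krt18 and Krt7) and 2 lower (Epcam and Cd74), with camera adjusted p of 0.703, 0.982 and 0.982. Adjusted over the list alone these were 2 and 2, 3 and 2, and 3 and 2. Krt18, a keratin, stood at 11.3 and 40.2 CPM. Medians and tests differed in sign for chromatin regulators, Hippo genes, sperm markers and oviduct, stroma or blood markers.

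Genes were also grouped by their change between stages in WT embryos, with each class called on libraries other than the WT library it was compared with. The decay class, genes at least 4-fold lower at L2C than at PN3, held between 2513 and 2685 genes. At L2C its median lay 0.56 ± 0.035 higher in KO on the log2 scale relative to genes in neither class (SD over the 3 held-out WT libraries, range 0.53 to 0.60). The zygotic class, genes at least 4-fold higher at L2C, held between 5887 and 6296 genes and differed by -0.94 ± 0.108 in KO (range -1.01 to -0.81). The 3 values of a class share the same KO mean, so these SDs hold no spread between KO libraries. A similar calculation compared 2 single WT libraries, with classes called on the third library of the stage. It gave differences of at most 0.0493 for the decay class and 0.187 for the zygotic class. Between WT replicates 1 and 2, which are not known to be separate samples, they were 0.00095 and -0.0064. At PN3 the decay class differed by 0.031 (range -0.069 to 0.217) against up to 0.362 between WT libraries, so no difference was detectable. The zygotic class differed by 0.020 at PN3, where most of its genes had few or no counts.

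**Figure D3:**
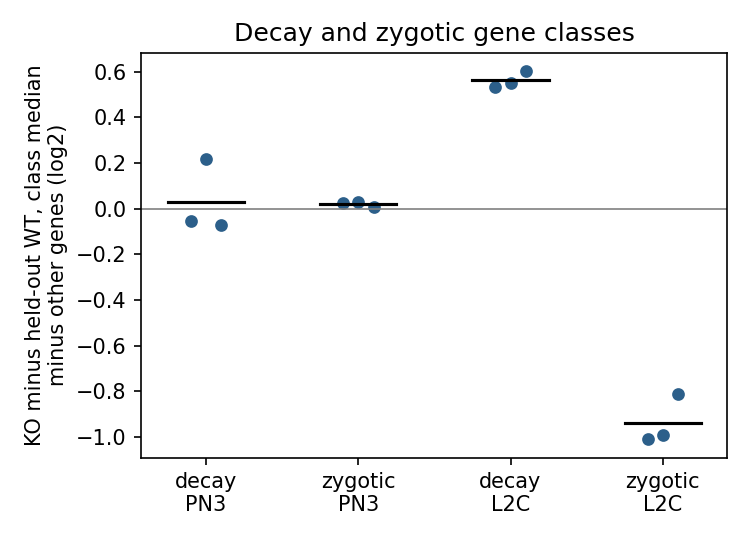
Median difference between KO and a held-out WT library (log2) for the decay and zygotic classes, relative to genes in neither class, at PN3 and L2C. Points are the 3 held-out WT libraries and the black line is their mean. At L2C the decay class lies at 0.56 and the zygotic class at -0.94.

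The third comparison described the change between the stages in each genotype. In WT embryos ribosomal protein genes rose (83 of 88 higher, 1 lower), for instance Rpl10a from 6.44 ± 0.8 to 323.3 ± 6.16 CPM (SD, n = 3 each). Genes of the minor wave of activation rose as well (39 of 45 higher, 3 lower), while maternal oocyte factors fell (44 of 56 lower, 4 higher), for instance Oas1d from 2991 to 127 CPM. Camera with an estimated correlation gave an adjusted p of 0.0741 for ribosomal proteins, 0.268 for the minor wave and 0.0891 for maternal oocyte factors. Nop16, a nucleolar protein, and Zfp352, a gene of 2-cell embryos, had 0 counts in WT PN3 and stood at 292 ± 42.8 and 270.6 ± 128.5 CPM in WT L2C, at least 6763-fold and 6314-fold higher.

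In WT, 13040 of 21160 genes passed in edgeR, 7668 higher and 5372 lower at L2C, and in KO 11334 passed, 7083 higher and 4251 lower. With the trend on GC content removed the splits were 6481 and 7447 in WT and 5709 and 6578 in KO, and with the trend on gene length removed 6403 and 7018 in WT and 5623 and 6111 in KO. Scaling by library size alone moved the median of all genes by 0.35 in WT and 0.42 in KO and gave 8409 higher and 2827 lower in KO, and DESeq2 size factors moved it by 0.26 and 0.15. Folr1, Bex6 and Rfpl4b were at least 6225-fold, 3811-fold and 3594-fold higher at L2C in WT, and Ccdc3 fell from 147.1 ± 17.7 to 2.25 ± 0.45 CPM (log2 fold change -6.03, SE 0.35, edgeR adjusted p = 6.36e-08). Zc4h2, Myzap and Cldn8 fell in WT from 14.1 to 0.17, from 10.6 to 0.14 and from 44.2 to 0.71 CPM, and Speer4f2 had 1 count in WT L2C. In KO, Trim43a, Obox8, Scd1 and Gstm1 were at least 3452-fold, 1384-fold, 1370-fold and 1352-fold higher at L2C, Crxos had 1 count in KO PN3, and Edn1, Sbk3, Stk32c, Myzap and Pms1 were lower, the last from 164 to 3.85 CPM.

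Camera called 7 lists in WT. Of these the major activation regulators (27 of 37 higher, 3 lower) held with an estimated correlation (adjusted p = 0.0441, and 0.0725 when the replicate block was added), and the others had an adjusted p with an estimated correlation of 0.0741 for ribosomal proteins and for ribosome biogenesis (66 of 90 higher, 11 lower), 0.0891 for maternal oocyte factors, 0.268 for the minor wave, 0.308 for nuclear oxidative phosphorylation (54 of 88 higher, 16 lower) and 0.13 for oviduct, stroma or blood markers (7 of 14 higher, 1 lower). Adjusted over the list alone these counts were the same, except 47 lower maternal factors. The marker list lost its call with the block (camera adjusted p = 0.122), while mitochondrial mRNAs (10 of 13 higher, 0.000936) and chromatin regulators (14 of 49 higher, 22 lower, 0.0463) gained one, with an adjusted p of 0.345 and 0.461 when an estimated correlation was added to the block. Mitochondrial mRNAs also passed with DESeq2 size factors (camera adjusted p = 0.0366, and an adjusted p = 0.631 with TMM and an estimated correlation). Among these markers Epcam rose from 1.40 to 153 CPM. Medians, means and tests differed in sign for deadenylation, poly(A), histone, spliceosome, cell cycle and Hippo genes. In KO, 80 of 88 ribosomal protein genes were higher and 43 of 56 maternal factors lower, and of the 10 lists called 0 held with an estimated correlation, while fry called 17. Cell cycle genes lost their call with library size only (camera adjusted p = 0.0685). With the block, oviduct, stroma or blood markers (7 of 14 higher, 0 lower) lost their call (camera adjusted p = 0.00361, and 0.0828 with the block). Poly(A) binding and polyadenylation genes (7 of 32 higher, 13 lower) and the proteasome (15 of 48 higher, 18 lower) gained one (0.0549 and 0.135, and 0.0214 and 0.0233 with the block, or an adjusted p of 0.158 and 0.258 with block and estimated correlation).

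The last comparison asked whether the effect of the deletion differed between the stages. Taldo1 was higher in KO at PN3 and lower at L2C (104 ± 11.8 CPM in WT L2C and 35.0 ± 1.85 CPM in KO L2C, SD, n = 3 each), an interaction of -3.27 on the log2 scale (SE 0.29, edgeR adjusted p = 0.000771). Uspl1, with 14.7 CPM in WT and 31.1 CPM in KO at PN3 and 205 and 89.0 CPM at L2C, had an interaction of -2.29. Psenen, a subunit of gamma-secretase, had 412 and 351 CPM in WT and KO at PN3 and 32.1 and 248 CPM at L2C, an interaction of 3.18 (SE 0.41, edgeR adjusted p = 0.00312). The interaction was 3.86 for Pan2 (SE 0.59, edgeR adjusted p = 0.00615). Grm4 (2.36), Samd10 (2.35), Gcc2 (2.56) and Krt8 (4.60) were the other named positive genes and Ecd (-2.76), Dhx8 (-2.62) and Abt1 (-2.74) the other negative ones.

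The interaction passed in edgeR for 1046 genes, 392 positive and 654 negative, or 695 positive and 443 negative with upper quartile scaling, which moved the median of all genes by 0.23. The count was 3772 with a replicate block within stages and 18 with L2C replicates 1 and 2 summed. The count was 6056 without the rRNA-rich libraries, a fit whose shared spread rests in part on the close L2C pairs. It was 464 and 578 without WT PN3 replicates 1 and 3, 529 and 546 without KO PN3 replicates 1 and 3, 281 and 279 without WT L2C replicates 1 and 2, and 366 and 391 without KO L2C replicates 1 and 2. Camera called 9 lists, of which ribosome biogenesis (22 of 90 negative, 51 adjusted over the list alone; adjusted p = 0.00227 with an estimated correlation) and the major activation regulators (3 of 37 negative, 5 adjusted over the list alone; 0.0323) held. The adjusted p with an estimated correlation was 0.0852 for ribosomal proteins (34 of 88 negative, 61 adjusted over the list alone), 0.12 for nuclear oxidative phosphorylation (7 of 88), 0.12 for the proteasome (10 of 48), 0.098 for the spliceosome (9 of 47), 0.246 for cell cycle genes (5 of 54), 0.681 for maternal oocyte factors (4 of 56 positive, 1 negative) and 0.796 for the minor wave (2 of 45 positive, 2 negative), whose call was lost with the block (camera adjusted p = 0.0644). With block and estimated correlation the adjusted p was 0.0383 for ribosomal proteins, oxidative phosphorylation and the spliceosome and 0.0457 for the proteasome. The minor wave also lost its call with DESeq2 size factors (camera adjusted p = 0.0615), and cell cycle genes lost theirs with upper quartile scaling (0.0863) or library size only (0.0824). Signs of median, mean and test differed for mitochondrial mRNAs, histones, p53 genes, chromatin regulators and sperm markers.

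Calls shared by both stages were few. Mfhas1, Chst9 and Tln2 were higher in KO at PN3 and at L2C, and Pan2, Glb1, BC003965 and Gm43269 were lower at both. Mfhas1 stood at 14.2 and 81.9 CPM in WT and KO at PN3 and at 2.37 and 18.7 CPM at L2C. Independent lists of these sizes would share 1.37 increases and 0.877 decreases, and 7 genes higher at PN3 were lower at L2C. Across genes, which are not independent replicates, the log2 fold changes of the 2 stages correlated with r = 0.041. With a replicate block 94 increases and 107 decreases were shared, where independent lists would share 45.1 and 45.5, while 102 genes higher at PN3 were lower at L2C and 46 genes lower at PN3 were higher at L2C.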

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

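The tests of the rRNA gene and of GC content in single libraries, of X-linked and Y-linked genes, of regression to the mean and of a share of PN3-like embryos were chosen only after the result was seen.

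The effect of the deletion differed between PN3 and L2C by the interaction term for 1046 genes. For named genes the KO effect at L2C minus that at PN3, in log2 units, was 3.86 for Pan2, -6.20 for Cdc5l, -2.62 for Efna1, -3.01 for Tmem159, -3.27 for Taldo1, -1.43 for Klhl12, -2.10 for Dppa5a, -1.76 for Gli2, -1.52 for Marchf7, -1.39 for Bub1b, 1.41 for Gipc2, 5.21 for Crmp1, 3.52 for Trpm4, 3.90 for Dusp2, 2.88 for Tpp1 and 2.54 for Nadsyn1. It was -10.63 for Stk33 and -12.32 for Ube2dnl1, values that depend on the prior count, since these had 0 counts and 1 count in KO L2C. Of 60 splits with genotypes shuffled within stages, 4 gave as many genes as the real 1046, the real one included, and the highest other gave 1752. For the 9 lists called, 3 of 60 splits gave as many, with 10 in the highest other. By these shares chance is not excluded, but the other splits that reached the real values all kept the genotypes apart at L2C and mixed them at PN3, so they hold the difference at L2C and are no measure of chance alone. The splits that mixed the genotypes at L2C gave 0 genes each. Such mixing puts the difference at L2C into the spread within groups, so these values are no measure of chance either.

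For the other counts the libraries make 10 splits, too few for a share under 0.05. The real split gave 28 genes at PN3, 3593 at L2C, 13040 between stages in WT and 11334 in KO, and the highest other split gave 0 in each case, so that 1 of 10 splits reached the real count. Each other split mixes the groups and so puts their difference into the spread within groups, so a count of 0 there is no measure of chance. Within PN3 and within L2C the 3 other splits that part as many same-numbered pairs gave 0 genes as well, and the others keep some same-numbered pairs together. Between the stages numbers were not taken to pair libraries. Of the 10 splits at PN3, all 10 gave at least the 0 lists of the real one, with 7 in the highest other, while those parting as many pairs gave 0. For lists at L2C and between stages in WT, 5 of 10 splits each reached the real 7, with 9 and 8 in the highest other.

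In each group 1 rRNA-rich library stood apart from the others. With CT010467.1 left out before scaling, 100.1% of the mean squared deviation of these 4 libraries remained, but TMM scaling already takes up a single dominant gene and the deviations of the other libraries hardly moved either, so what the share of that gene goes with cannot be told apart by this value. With the trend on GC content removed 92.5% remained, which argues against that trend as the whole cause, although deviations in these libraries correlated with GC content across genes by 0.161 to 0.312. Since the groups hold 1 such library each, no biological explanation was tested, and a step of library preparation, for which the labels give no record, stays open.

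At L2C the decay class was higher and the zygotic class lower in KO. WT L2C replicates 1 and 2 are not known to be separate samples, so holding out WT replicate 3 best keeps class and comparison apart. Against it the decay class differed by 0.60 and the zygotic class by -0.81, with at most 0.0493 and 0.187 between WT libraries. These values argue against regression to the mean as the whole cause. The lowest ratio of a cross-fitted median to the largest difference between WT libraries was 4.34. With the trend on GC content removed it was 4.27, which argues against that trend as the whole cause. Differences between WT libraries hold no spread between KO libraries. A share of PN3-like embryos, as the only cause, would be the same for both classes. The zygotic class needed 45.5% to 51.3% over the held-out libraries and the decay class 9.57% to 10.3%, on average 39.3 percentage points less. This argues against such embryos as the only cause of both differences. A smaller share of them, as the decay class would need, is not excluded. Embryos delayed at another stage stay open, since no such profile was measured. As described under processing, levels are those of RNA with a poly(A) tail long enough to be primed. A difference in tail length, between genotypes or between stages, is therefore not told apart from a difference in RNA amount.

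X-linked genes of the zygotic class lay below autosomal ones in KO L2C, with differences of -0.47, -0.56 and -0.12 on the log2 scale against the 3 held-out WT libraries. Fewer female embryos in the KO pools would raise Y-linked zygotic genes relative to autosomal ones, and this difference was 0.231 on average but -0.11, -0.15 and 0.94 singly over 9 to 12 genes, so a sex difference cannot be told apart with so few genes. A general lower level of zygotic genes cannot be told apart either, since the X-linked median lay below all 1000 autosomal sets matched on rise and level in 2 of the 3 comparisons and inside their range against WT replicate 3. An effect on the X chromosome itself was not tested.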

How the results depend on the processing

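Chosen after seeing the data were the within-stage replicate block, with or without GC trend or estimated correlation, the fits without the rRNA-rich libraries or with them as a covariate, the GC trend, the summed L2C replicates, and the fit without CT010467.1. The within-stage replicate block gained 47 calls among the single genes examined and lost 0. It was chosen from these same counts, so these gains are no separate support. For genes and lists its changed calls are given in the comparisons where the report names them, and it changed no other call among those. In simulated libraries fitted without a block 5% of 2-fold changes at PN3 and 8% at L2C were called. Only genes of at least 5 CPM in WT were changed there. A missing call at this depth and spread is therefore no evidence of an equal level. The cause was not tested for any change below, except that fewer genes were tested with the stricter filter, that a test against 1.5-fold asks for more, and that fewer libraries remain in leave-one-out and summed fits.

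Genes called at PN3 (28) were 538 by the DESeq2 Wald test, 78 with no filter, 53 with a stricter filter, 2 with only the groups compared in the fit, 9 with a replicate block across stages, 6 with that block and the length trend removed, 12 against 1.5-fold, 566 with the within-stage replicate block, 2038 without the rRNA-rich libraries, 613 with them as a covariate, 79 with the GC trend removed, 797 with GC trend removed and within-stage block, and 1 with L2C replicates summed. Genes called at L2C (3593) were 1488 against 1.5-fold, 6815 with the within-stage replicate block, 9524 without the rRNA-rich libraries, 6971 with the covariate, 7217 with GC trend removed and block, and 379 with L2C replicates summed. The fit without rRNA-rich libraries leaves at L2C the close pairs of replicates. Their spread enters the shared estimate, and so also the counts for PN3, the interaction and the overlap of calls in that fit. Interaction calls (1046) were 619 with library size only, 2741 by Wald test, 641 with a replicate block across stages, 319 against 1.5-fold, 3772 with the within-stage replicate block, 6056 without rRNA-rich libraries, 3863 with the covariate, 4178 with GC trend removed and block, and 18 with L2C replicates summed. With the stricter filter 7655 genes passed between stages in WT and 6514 in KO.

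The overlap of calls (7) was 11 with DESeq2 size factors, 142 by Wald test, 15 with the stricter filter, 3 with a replicate block across stages, 201 with the within-stage block and 754 without rRNA-rich libraries. Lists called with an estimated correlation were 2 at L2C, 1 between stages in WT and 2 for the interaction, and by fry 11 at L2C and 15 between stages in WT. With the within-stage replicate block and an estimated correlation 0 lists were called between stages in WT, where camera with that block called 8 and fry without it 15. At PN3 1 list, chromatin regulators, was called without rRNA-rich libraries.

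The decay class at L2C (0.56) was 0.396 at a log2 fold of 1, 0.646 with classes from all WT libraries and 0.733 without rRNA-rich libraries. The zygotic class at PN3 (0.020) was 0.036 with classes from all WT libraries, 0.0024 with DESeq2 size factors, 0.046 with library size only, 0.0055 without rRNA-rich libraries, and -2.36e-05 with the stricter filter, a change of sign near 0. The zygotic class at L2C and the decay class at PN3 moved by less than their spread between libraries under each alternative run, but the latter (0.031) changed sign, at -0.038 without KO PN3 replicate 1 and -0.040 without replicate 3, and was 0.140 without replicate 2.

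Leaving out each library in turn gave 1 to 38 genes at PN3, 1574 to 3551 at L2C, 279 to 1357 for the interaction, 0 to 1 lists at PN3, Pan2 log2 fold changes of -1.945 to -1.286 at L2C, 0.499 to 0.679 for the decay class at L2C and 0.0172 to 0.0408 for the zygotic class at PN3. Counted per gene, comparison and left-out library, results of single genes named lost a call in 370 cases and gained 1 in 17. They moved in 12 cases and stayed the same in 2925. Other settings gained 42 calls and lost 0 (Wald test), gained 8 and lost 2 (DESeq2 size factors), gained 3 and lost 31 (library size only), lost 29 (replicate block across stages), gained 47 (within-stage block), and gained 64 and lost 1 (without rRNA-rich libraries). Of list results, 18 calls were lost with an estimated correlation, fry gained 14 and lost 2, the within-stage block gained 4 and lost 2, and leaving out libraries gained 12 and lost 9.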

Other observations

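The tests of matched lists and of further machinery lists were written down before their own results were seen, but both were thought of only after the lower lists of the report had been seen.

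Further lists of genes linked to translation and transcription machinery were lower in KO L2C as well. Of 77 mitochondrial ribosomal protein genes 37 were lower and 3 higher (median log2 fold change -0.79), of 26 RNA polymerase subunits 13 were lower and 0 higher (median -0.85), of 50 genes with symbols of translation initiation factors and their regulators 16 were lower and 1, the kinase gene Eif2ak4, higher (median -0.50), of 21 tRNA synthetases 7 were lower and 0 higher (median -0.53), and of 8 CCT chaperonin genes 2 were lower and 0 higher (median -0.83). Camera at the preset correlation called 5 of these 5 lists, and with an estimated correlation the adjusted p was 0.021, 0.00956, 0.021, 0.021 and 0.184 in that order. The RNA polymerase list shares Polr1a, Polr1b, Polr1c, Polr1d and Polr1e with ribosome biogenesis, and the other 4 share no member with the lists of the report. At PN3 mitochondrial ribosomal proteins and tRNA synthetases passed camera with the within-stage replicate block only (adjusted p = 0.041 each, and 0.0833 and 0.158 without it), and without the block the adjusted p with an estimated correlation was 0.727 and 0.399. Oocyte gene families went the other way, with 14 of 36 members higher and 1 lower (camera adjusted p = 1.13e-05, and an adjusted p = 0.333 with an estimated correlation), and share Oas1d, Obox5, Omt2a, Omt2b, Oog1 and Tcl1b1 with the maternal oocyte factors, Btg4 with deadenylation and Obox1, Obox2, Obox3 and Obox6 with the minor wave.

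A hypothesis was that growth-related lists lay low in KO L2C only because such genes rise between the stages. In 4 of 5 lists the median lay below the central 95% of 1000 random lists matched on the WT change between stages and on level, which argues against it as the whole cause. These were ribosomal proteins (-1.36, matched median -1.14), ribosome biogenesis (-1.09, matched -0.68), the proteasome (-0.87, matched -0.24) and the spliceosome (-0.74, matched -0.23). Nuclear oxidative phosphorylation (-0.62, matched -0.49) lay inside that range, as did the major activation regulators (-0.81, matched -0.78) and maternal oocyte factors (0.56, matched 0.49), while the minor wave (-0.71, matched -1.02) lay above it. Members of a list are correlated and the matching shares the WT L2C libraries, so these ranks describe these libraries only.

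Pan3, the partner subunit of Pan2, was chosen after its values were seen. It stood at 295.54 CPM in WT L2C and 443.24 CPM in KO L2C, a log2 fold change of 0.585 (SE 0.19, edgeR adjusted p = 0.0494), with an interaction that missed the threshold (edgeR adjusted p = 0.283).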
